A study of Mus musculus with 2 samples.

How the data were processed

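Cardiac myofibroblasts of mouse were measured by RNA sequencing in 2 libraries, 1 from cells given a control siRNA and 1 from cells given an siRNA against Bcat1, and the groups were taken from the treatment label of each sample. Per the labels' protocols, total RNA was extracted with a column kit and libraries were built by a sequencing service with a stranded mRNA kit from Illumina. FastQC, Trimmomatic, HISAT2, StringTie and genome build mm10 are named, per the submitters' processing notes, without versions. Which step each tool did, its settings, whether strand was used in counting, and whether single reads or read pairs were counted are not given in the sources used here. The table of gene counts holds whole numbers of reads per gene, not normalized, per the file headers and the values, as deposited by the authors. The TPM values (abundances scaled for transcript length and depth) were made by the authors, per the file headers, and sum to 998462 in siControl and 998120 in siBcat1. The count table lists 24532 genes with Entrez identifiers and RefSeq transcript accessions, each symbol in 1 row, with 8957 genes at 0 in siControl and 9592 in siBcat1, and no gene with a mitochondrial symbol prefix.

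Counts were scaled with trimmed mean of M values factors (TMM) from edgeR 4.0.16 in R 4.3.3, which were 1.03 for siControl and 0.969 for siBcat1. Library totals were 127309329 and 104581819 counts. No test was made and no p-value is given, because each group has 1 library. The log2 fold is siBcat1 over siControl in scaled counts, and each fold has an exact (Clopper-Pearson) 95% interval from the binomial share of the siBcat1 count in both counts. These intervals cover counting error only, and if the mates of a pair were counted separately they are too narrow. A gene at 0 in 1 library was set against a floor of 3 counts, which equals 0.0228 CPM in siControl and 0.0296 CPM in siBcat1. Genes with a mean of at least 5 CPM over both libraries were kept, 9935 in number, of which 224 are predicted or unnamed models. Genes at least 2-fold higher or lower were counted as a rule of size.

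The following were set before the data were examined. The gene lists numbered 42, of which 31 hold pathways and 11 hold cell type markers. For lists with at least 5 measured members, the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. Bcat1 was left out of list medians. Named genes were Bcat1 and Bcat2; the 15 genes with the highest and the 15 with the lowest log2 fold, without predicted or unnamed models; the 8 highest and 8 lowest among genes of at least 100 CPM; up to 4 members of each list with the largest absolute log2 fold; and the genes the study centres on, which are Aldh18a1, Pycr1, Pycrl, Prodh, Col1a1, Col1a2, Col3a1, Acta2, Postn, Fn1 and Tgfb1. Single values of a few genes that the rule names are not reported here. The alternatives were DESeq2 1.42.0 size factors, library totals, upper-quartile factors, the TPM values with a pseudocount of 1 or 0.1, minimum CPM of 1 or 20 or none (with a prior count of 0.5), leaving out predicted models, thresholds of 1.5-fold and 3-fold, whole intervals past 2-fold, list means, and 10 or 50 expression bins.

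Correction for transcript length was added after the length trend had been seen. Lengths came from GENCODE M21 transcripts (GRCm38) matched by RefSeq accession, with a length for 9927 of the 9935 genes. A lowess curve of log2 fold on log2 length, with a fraction of 0.3 and 3 iterations in statsmodels 0.14.6, was subtracted from each fold. The curve accounted for 38.0% of the variance of the log2 folds. Versions of the same correction used the length that counts and TPM imply, and length together with GC content. Intervals of gene group medians and their differences, given with the tests in the closing section, are 95% bootstrap intervals over genes (1000 draws) and not counting intervals. For sequence words in the 3' UTR, lowess trends on 3' UTR length and then on 3' UTR GC content were subtracted from the length-adjusted folds as well, and these folds were limited to within 2 for scoring words. Coordinates are those of GENCODE M21, counted from 1. Overlapping gene models and gene families with near-identical copies were also summed, because the counting could have split their reads. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

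The scripts' calculations were tested on simulated data. In counts drawn for 9934 genes of which 200 were changed, 94.7% of intervals held the true fold, all changed genes had the right direction and 0 unchanged genes passed 2-fold. Both libraries were drawn with counting error alone. The result therefore does not tell how many unchanged genes would pass 2-fold between real cultures. Of 200 simulated lists with no effect, 7% passed either percentile limit. In a simulation of a length trend, a list lowered by 0.6 had a median of -1.26 before and -0.60 after the trend was removed. Length ordered the simulated folds almost fully (Spearman -0.9965), far more than in the libraries (-0.657). The simulation therefore checks the calculation and not how well the correction works on these data.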

Results

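Messenger RNA was profiled in mouse cardiac myofibroblasts, the contractile and matrix-secreting form that fibroblasts take in injured heart tissue. The cells came from C57BL/6 hearts 3 days after myocardial infarction and were transfected with 12.5 nM of a control siRNA (siControl) or of an siRNA against Bcat1 (siBcat1), then cultured for 72 hours. Bcat1 encodes the cytosolic branched-chain amino acid aminotransferase, which moves the amino group of leucine, isoleucine and valine onto 2-oxoglutarate. Each group had 1 library, so there are no replicates, no spread between replicates and no replicate check of any difference given here. The siControl library held 127309329 counts over 15575 detected genes and the siBcat1 library 104581819 counts over 14940 detected genes. Eef1a1 took the largest share of counts in both libraries, with 1.56% in siControl and 2.10% in siBcat1. After scaling, 1 CPM, the unit of counts relative to library size, equalled 131 counts in siControl and 101 counts in siBcat1. Intervals in brackets beside single genes are exact 95% intervals of counting error only and hold no spread between replicates. They take reads as independent, which reads amplified by PCR are not, so they are too narrow to that extent.

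The comparison addresses whether lowering Bcat1 goes with lower expression of proline synthesis and matrix genes. Bcat1 itself (chromosome 6, 144993835 to 145076184, minus strand, GRCm38) had 8891 counts in siControl and 99 in siBcat1, a log2 fold of -6.11 [-6.41 to -5.83], and none of the 500 genes nearest to it in expression differed as much. Collagen and other matrix genes were lower with siBcat1, interferon-stimulated, antioxidant and ribosomal protein genes were higher, and the proline synthesis genes went both ways. Bcat2, the mitochondrial aminotransferase, had 5175 and 4477 counts, a log2 fold of 0.17 [0.11 to 0.22], which had the opposite sign with the deposited TPM values (-0.33) and with the trend on transcript length removed (-0.10), and was 0.03 with length and GC trends removed. The Bcat1 fold was -4.00 on the log2(TPM + 1) scale, which understates differences of genes with low values.

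Of 9935 genes with a mean of at least 5 CPM, 554 (5.58%) were at least 2-fold higher with siBcat1 and 1292 (13.0%) were at least 2-fold lower. The split depended on the scaling, with 823 higher and 1018 lower under upper-quartile factors, and 112 higher and 1971 lower with TPM. The median log2 fold of all genes was -0.06. It shifted by 0.13 under upper-quartile factors and by -0.41 with TPM, where 8811 genes passed the minimum. Small folds therefore have no firm direction apart from that shift. Among the 1902 genes with a mean of at least 100 CPM, 160 were at least 2-fold higher and 170 at least 2-fold lower.

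Transcript length ordered the folds. Across 9927 genes, which are not independent replicates, the log2 fold and transcript length had a Spearman correlation of -0.657 and a Pearson correlation, on log2 length, of -0.613. When genes were parted into 10 groups by length, the median log2 fold was 0.74 in the shortest group, with transcripts of up to 1226 bases, and -1.01 in the longest, with transcripts of at least 6242 bases. In the shortest group 25.5% of genes were at least 2-fold higher, and in the longest 50.8% were at least 2-fold lower. With the trend removed, 410 genes were at least 2-fold higher and 530 lower, among them 196 of the higher and 476 of the lower genes counted before. Each gene group is therefore given with its median transcript length and its median after removal of the trend, called length-adjusted.

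**Figure D1:**
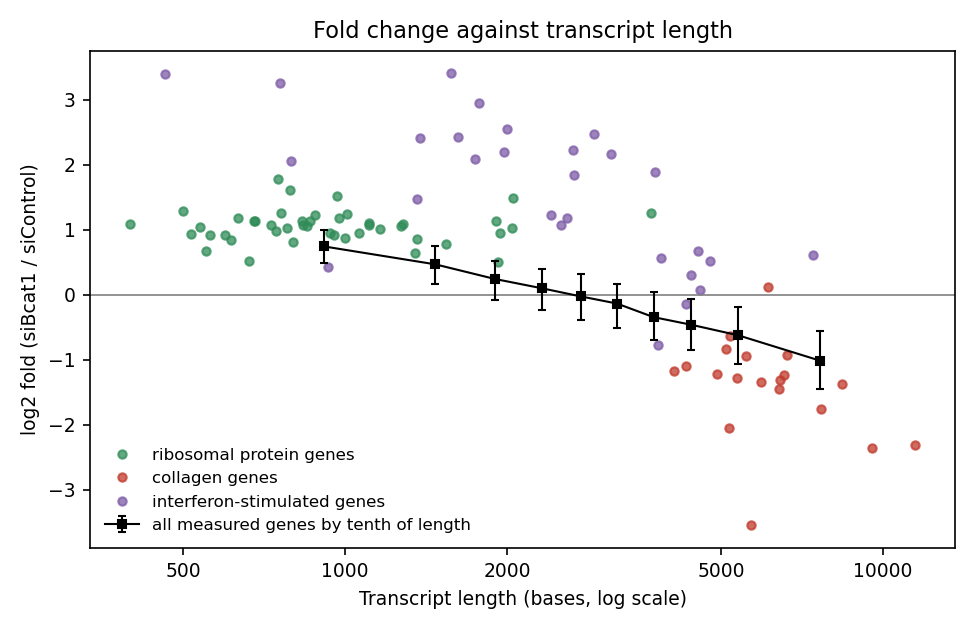
The log2 fold (siBcat1 over siControl) is plotted against transcript length in bases on a log scale, with squares for the median and bars for the middle 50% of all measured genes in 10 groups by length, and points for single collagen, interferon-stimulated and ribosomal protein genes. The group medians run from 0.74 for the shortest to -1.01 for the longest transcripts.

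Proline synthesis genes were divided. Aldh18a1, which encodes the enzyme that commits glutamate to proline (chromosome 19, 40550257 to 40588463, minus strand), had a log2 fold of -0.91 [-0.94 to -0.87], from 191 to 102 CPM. Pycr1, the mitochondrial reductase of the last step (chromosome 11, 120635712 to 120643769, minus strand), had -0.63 [-0.70 to -0.56]. The related reductase gene Pycrl had 0.65 [0.58 to 0.71]. Length-adjusted, these 3 genes had -0.67, -0.70 and 0.14, in the same order. Gpt2, an alanine aminotransferase in the same list, had -1.37 (length-adjusted -1.09). Of the 9 measured members of the list, 2 were at least 1.5-fold higher, 3 were at least 1.5-fold lower and 4 lay between. The list median was 0.19, at percentile 77.1 of 10000 random lists matched on expression, with a median length of 2387 bases and a length-adjusted median of 0.12. With TPM the list median was -0.31, and the mean of the members was -0.13. Prodh, which starts proline breakdown, had 163 and 160 counts and lay below the expression minimum. Of the 5 listed genes for breakdown of proline and hydroxyproline, 2 were measured, Pepd with 0.19 and Aldh4a1 with 0.13, and both lay within 1.5-fold.

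**Figure D2:**
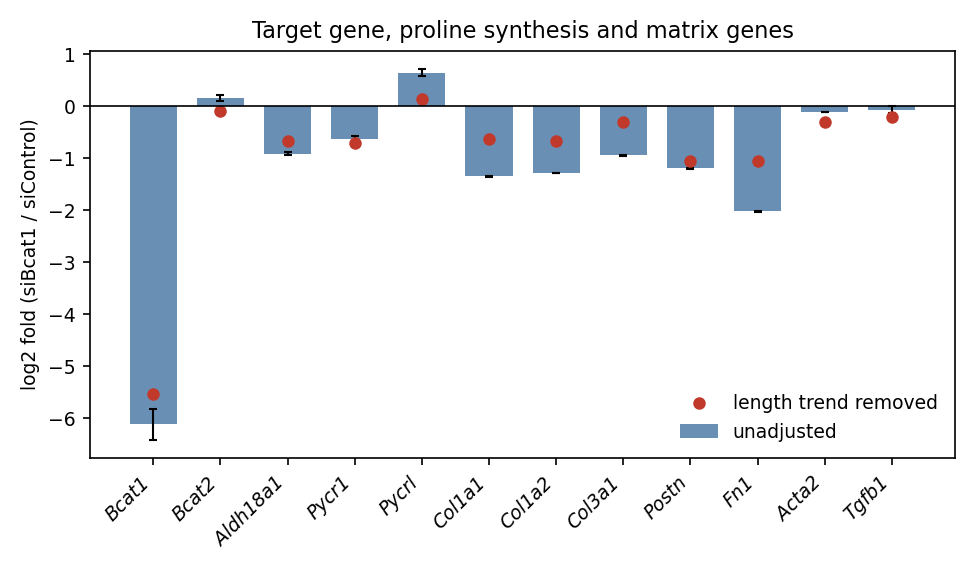
Bars show the log2 fold (siBcat1 over siControl, 1 library each) of the target gene, proline synthesis genes and matrix genes, with 95% intervals of counting error, and dots show the value after removal of the length trend. Bcat1 stands at -6.11, Fn1 at -2.02 and Pycrl at 0.65.

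Collagen genes were lower almost throughout. The list of fibrillar and basement membrane collagens also holds other types, such as Col6a3, Col12a1 and Col14a1. Of its 19 measured members, 18 were at least 1.5-fold lower, none was at least 1.5-fold higher and 1 lay between. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) had a log2 fold of -1.35 [-1.35 to -1.34], from 11058 to 4345 CPM. Col1a2 (chromosome 6, 4504814 to 4541544, plus strand) had -1.28 [-1.29 to -1.28] and Col3a1 (chromosome 1, 45311538 to 45349706, plus strand) had -0.94 [-0.95 to -0.94]. Length-adjusted, these 3 genes had -0.63, -0.67 and -0.29. The lowest members were Col14a1 with -3.55, Col6a3 with -2.36, Col12a1 with -2.31 and Col15a1 with -2.06 (length-adjusted -2.87, -1.23, -1.02 and -1.47). The list median of -1.28 was below all 10000 random lists. Its members had a median length of 5930 bases, and the length-adjusted median of -0.65 was again below all random lists, with 11 members at least 1.5-fold lower and 1 higher. With length and GC trends removed, the median was -0.48 (percentile 0.01), Col1a1 had -0.44 and Col3a1 -0.14.

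Genes for collagen processing and crosslinking had a median of -0.42 (percentile 0.38), with 8 of 24 measured members at least 1.5-fold lower, 1 higher and 15 between. With a median length of 3080 bases, they had a length-adjusted median of -0.32 (percentile 0.11). Loxl2, a lysyl oxidase that crosslinks collagen, had -1.64 and a length-adjusted value of -1.52. P4ha3, a subunit of collagen prolyl hydroxylase, had -1.59 (length-adjusted -1.66), and Serpinh1, the collagen chaperone, had -1.15 (length-adjusted -1.28). The other matrix and matricellular genes had a median of -0.82, below all random lists, with 17 of 31 measured members at least 1.5-fold lower, 3 higher and 11 between. Their median length was 3120 bases and their length-adjusted median -0.48. Fn1, which encodes fibronectin, had -2.02 [-2.02 to -2.01] (length-adjusted -1.06), from 11958 to 2955 CPM. Fbn2, a fibrillin, had -3.34 and Wisp1, a matricellular protein gene, had -2.24, while Spp1, which encodes osteopontin, was higher with 2.64 (length-adjusted -2.08, -1.67 and 2.18). Periostin (Postn) had -1.19 [-1.21 to -1.17] and -1.04 length-adjusted. Matrix proteases and their inhibitors did not stand apart except with TPM, where the list was lower. Their median was -0.19 (percentile 11.2; median length 2525 bases; length-adjusted -0.13), with 4 of 17 members at least 1.5-fold higher and 5 lower. Mmp3 was higher with 2.22 and Timp1 with 1.27, and the metalloprotease genes Adam12 and Adam19 were lower with -1.71 and -1.31; length-adjusted, these 4 genes had 1.94, 0.55, -0.76 and -0.52.

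Contractile genes of myofibroblasts had a median of -0.40 (percentile 0.545), with 8 of 21 measured members at least 1.5-fold lower, none higher and 13 between. Members had a median length of 2460 bases and a length-adjusted median of -0.34 (percentile 0.1). The lower members included the non-muscle myosin heavy chain genes Myh10 with -2.13 and Myh9 with -1.26, filamin A (Flna) with -1.84 and alpha-actinin 1 (Actn1) with -1.27, and length-adjusted these had -1.17, -0.34, -0.83 and -0.96. Acta2, the smooth muscle actin used as the myofibroblast marker, had -0.11 [-0.11 to -0.10], with 0.02 under upper-quartile factors, -0.61 with TPM and -0.29 length-adjusted. Genes of the TGF-beta pathway had a median of -0.37 (percentile 1.92), with 11 of 27 measured members at least 1.5-fold lower and 1 higher. Their median length was 3443 bases, and the length-adjusted median of -0.07 (percentile 19.9) no longer stood apart. The ligand genes Tgfb2 and Tgfb3 had -1.24 and -1.14 (length-adjusted -0.67 and -0.93), and Tgfb1 had -0.06 [-0.12 to -0.00], with 0.07 under upper-quartile factors, -0.55 with TPM and -0.20 length-adjusted. Ldlrad4, an inhibitor of TGF-beta signalling, had -1.38 (length-adjusted -1.42).

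Among amino acid genes, the targets of the stress factor ATF4 had a median of -0.23 (percentile 11.6), with 10 of 28 measured members at least 1.5-fold lower and 2 higher. Their median length was 2174 bases, and the length-adjusted median of -0.30 stood apart (percentile 0.28), but the median of -0.18 after removal of length and GC trends did not (percentile 3.83). Trib3 had -1.78, Aldh1l2 -1.76 and Chac1 -1.39 (length-adjusted -1.97, -1.03 and -1.75), whereas Cebpb, a transcription factor gene, was the member with the largest difference and was higher with 5.89, from 124 to 5681 counts. Branched-chain amino acid genes other than Bcat1 had a median of 0.16 (percentile 90.5; median length 2500 bases; length-adjusted -0.03), with 3 of 20 at least 1.5-fold higher and 3 lower. Abat had -1.04 and Acad8 0.67 (length-adjusted -0.79 and 0.73). The aminoacyl-tRNA synthetases had a median of 0.01 (percentile 42.0; median length 2759 bases; length-adjusted 0.04), with 4 of 20 lower, none higher, and the lowest value in Wars with -1.10. Genes for amino acid sensing and mTORC1 had a median of -0.01 (percentile 59.8; median length 2749 bases; length-adjusted -0.17), with 9 of 24 lower and 3 higher, and among the lower ones were Deptor with -2.19 and Rptor with -1.65 (length-adjusted -1.47 and -0.83). The sign of this median turned with the filter, with 0.28 at a minimum of 20 CPM, and the list was called lower with the length that counts and TPM imply (-0.26, percentile 1.64). Endoplasmic reticulum stress genes had a median of -0.19 (percentile 9.09; median length 2461 bases; length-adjusted -0.10), with 5 of 21 lower, 2 higher, and the largest difference in Ern1 with -1.82 (length-adjusted -0.96); this list was called lower with TPM.

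Interferon-stimulated genes were higher with siBcat1. Of 28 measured members, 21 were at least 1.5-fold higher, 1 was lower and 6 lay between. Rtp4 had 3.41 [3.29 to 3.52], Ifi27l2a 3.39 [3.15 to 3.64], Isg15 3.26 [3.17 to 3.35] and Usp18 2.96 [2.80 to 3.11], from 3.03 to 23.5 CPM for Usp18. The median of 1.87 lay above all 10000 random lists, and so did the length-adjusted median of 1.66, at a median length of 2551 bases. Antigen presentation genes had a median of 0.49 (percentile 98.1), with 4 of 10 at least 1.5-fold higher and none lower, at a median length of 1710 bases. The length-adjusted median of 0.34 (percentile 96.9) no longer stood apart, nor did the list at a minimum of 20 CPM, with no minimum, or with TPM, where the median was -0.016; after removal of length and GC trends it did, with 0.48 (percentile 99.8). H2-T23 had 1.74 and Psmb8, a subunit of the immunoproteasome, 1.04 (length-adjusted 1.30 and 0.67). Cytokine and chemokine genes had a median of 0.32 (percentile 89.7; median length 2699 bases; length-adjusted 0.35, percentile 97.8), with 6 of 13 higher and 3 lower, and were called higher in 6 of 16 settings, with a median of 0.70 over 20 genes at a minimum of 1 CPM and 0.98 over 26 genes with no minimum. The monocyte chemoattractants Ccl7 and Ccl2 had 2.17 and 1.78, and Lif had -1.68 (length-adjusted 1.40, 1.02 and -1.34). Lyz2, the macrophage marker that passed the expression minimum, had 717 and 2159 counts, a log2 fold of 1.97 (length-adjusted 1.45).

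Antioxidant genes under NRF2 were higher as a group, with a median of 0.62 (percentile 99.99) and 14 of 26 at least 1.5-fold higher, 3 lower and 9 between. Their median length was 2089 bases and their length-adjusted median 0.52, above all random lists. The ferritin subunit genes Fth1 and Ftl1 had 2.57 and 1.68 (length-adjusted 2.01 and 1.00), the glutathione transferase gene Gsta4 had 2.99, and Txnrd1, a thioredoxin reductase gene, was lower with -1.70. Cytosolic ribosomal protein genes had a median of 1.07, above all random lists, with 43 of 45 at least 1.5-fold higher and none lower. These short transcripts, with a median of 860 bases, had a length-adjusted median of 0.33 (8 members at least 1.5-fold higher, none lower). Rps9 had 1.77 and Rps27a 1.60 (length-adjusted 0.98 and 0.83). Oxidative phosphorylation genes had a median of 0.58, above all random lists, with 17 of 35 at least 1.5-fold higher and none lower. At a median length of 1001 bases, the length-adjusted median was -0.03 (percentile 22.1); the call was also lost with TPM. Ndufa5 and Cox5a, subunits of the respiratory chain, had 1.45 and 1.27 before and 0.55 and 0.41 after adjustment.

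Cholesterol synthesis genes had a median of 0.43 (percentile 98.6; median length 3027 bases; length-adjusted 0.46), with 7 of 23 at least 1.5-fold higher, 3 lower and 13 between. Msmo1 and Fdps, enzymes of the pathway, had 1.46 and 1.45, while Dhcr7 had -1.35. With TPM the list median was -0.077, and the call was lost with TPM and for the mean of the members. Fatty acid and lipid genes had a median of -0.45 (percentile 0.6), with 9 of 22 lower and 3 higher, at a median length of 3305 bases. The length-adjusted median of -0.01 (percentile 35.0) no longer stood apart, nor did the list without an expression minimum or by its mean. Scd2 had -1.55 (length-adjusted -0.92), and Fasn, the fatty acid synthase gene, had -1.08 with the opposite sign after adjustment (0.09).

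**Figure D3:**
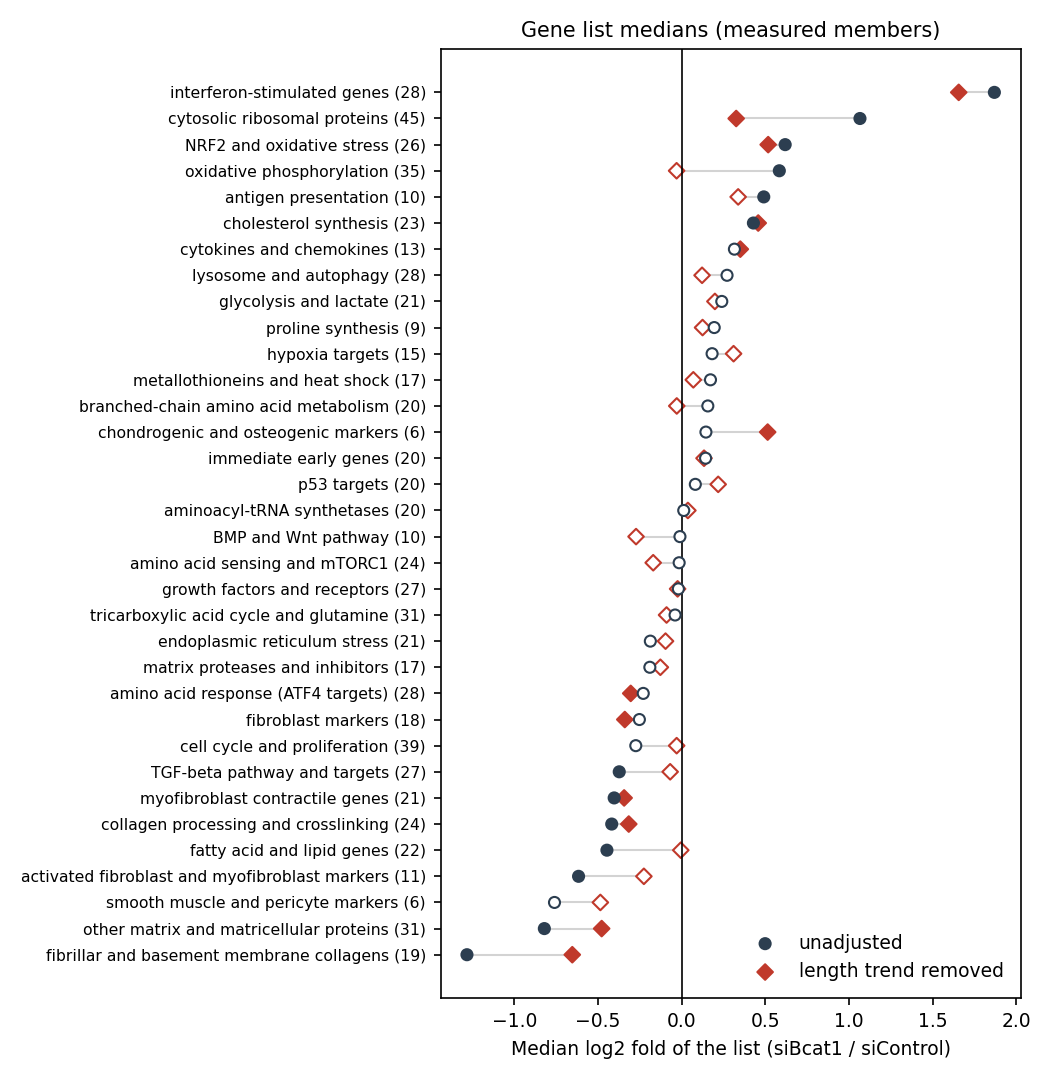
Each row gives the median log2 fold (siBcat1 over siControl) of a gene list, with the number of measured members in brackets; circles show the unadjusted median and diamonds the median after removal of the length trend, filled where the list stands apart from random lists. Collagens lie at -1.28 and -0.65, and interferon-stimulated genes at 1.87 and 1.66.

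In all, 34 lists had at least 5 measured members, and 6 stood apart as higher and 7 as lower. At the nominal rate of the limits 0.85 per side would, a rate that lists simulated with no effect exceeded (7% of 200 passed either limit). Neither rate gives the number to be expected here. The lists share members, such as Col1a1, and genes of a pathway can move together. The simulated lists held random genes in counts without a length trend. After removal of the length trend 6 were higher and 6 lower; 8 kept their call and direction, 5 lost it and 4 gained one. The collagen, collagen processing, other matrix, contractile, interferon-stimulated, NRF2 and ribosomal protein lists were called in the same direction in all 16 settings tried. A scaling factor shifts every fold alike, so under it a call can change only through the expression minimum and the matching on expression. The settings for bins and predicted models kept the same folds. The TPM and length settings changed folds gene by gene.

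Most of the largest differences of single genes lay outside these lists. The fusion model Dpm1-adnp had 2418 counts in siControl and 0 in siBcat1, a log2 fold of -9.28 or lower against a floor of 3 counts, but its reads overlap those of Dpm1 and Adnp, and the 3 models together had -0.04. Zscan26, a zinc finger gene, had -6.61 [-7.52 to -5.83], from 1647 to 13 counts, and Xylt1, which starts the sugar chains of proteoglycans, had -5.67 [-6.18 to -5.19]. Zbed6 had -5.32, but it lies inside Zc3h11a, and the pair together had -2.51. Celf2, an RNA-binding protein gene, had -4.41, Pik3r1, the regulatory subunit of PI3-kinase, -4.22 and Clock, a core gene of the circadian clock, -4.08. Among genes of at least 100 CPM, Ston1 had -2.91, the perlecan gene Hspg2 -2.49 (length-adjusted -1.02), Caprin1 -2.43 and Sumo3 -2.39. In the other direction, Prl2c3 had 7.45, with reads that near-identical Prl2c copies may share, and the 5 copies together had 3.36. Cebpb had 5.89 [5.64 to 6.16], Gzme, a granzyme gene of a family of close copies, 4.47, Esm1, a secreted proteoglycan gene, 4.34 and Gp1bb 4.02. Tmem254c had 3.93, and its 3 copies together 1.44. Hnrnpa1, an RNA-binding protein gene with many processed copies in the genome, was the abundant gene with the largest higher value, 3.04, and Plac8 and Sepw1 each had 2.20 (length-adjusted 1.40 each). Reads of Hnrnpa1, Fth1, Ftl1 and the ribosomal protein genes can be split with pseudogenes, so their folds are uncertain to that extent.

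Fibroblast markers made up 34940 CPM in siControl and 23982 CPM in siBcat1. The fall lay in 3 collagen genes of the list, and the other members together were not lower. Col1a1 went from 11058 to 4345 CPM, Col1a2 from 9534.5 to 3919 CPM and Col3a1 from 4638 to 2412 CPM. Of the 18 measured fibroblast markers, 4 were at least 1.5-fold higher and 5 lower. Their median was -0.25 (percentile 4.18) at a median length of 2476 bases, and the length-adjusted median was -0.34 (percentile 0.28). Cd34 had 1.42 and S100a4 1.31, against -1.47 for Pdgfrb, and length-adjusted these were 1.39, 0.34 and -0.85. Activated fibroblast and myofibroblast markers had a median of -0.62 (percentile 0.75), with 6 of 11 lower and none higher, at a median length of 4195 bases, and the length-adjusted median was -0.23 (percentile 6.81). The list was called lower in 14 of 16 settings, including removal of length and GC trends (-0.29, percentile 1.96). Lrp1 had -1.73 and Runx1 -1.09 (length-adjusted -0.23 and -0.68). The endothelial list summed to 504 and 351 CPM, mostly from Eng (-0.73), but its 4 measured genes had a median of 0.33, with Fabp4 at 1.44 and Egfl7 at 0.74 (length-adjusted 0.73 and 0.23). It was called higher in 4 of the 5 settings that measured enough members, among them a minimum of 1 CPM (median 0.63 over 10 genes, percentile 98.9). The cardiomyocyte list summed to 536 and 251 CPM, mostly from Atp2a2 (-1.04), which many cell types express, and its other measured member, the cardiac troponin gene Tnnt2, had 6091 and 1041 counts, a log2 fold of -2.17 [-2.27 to -2.08] (length-adjusted -2.77). The Schwann and neural list summed to 777 and 605 CPM, mostly from Tubb3 (-0.36), and was called lower with no minimum (-1.42 over 10 genes, percentile 0.71). Macrophage and monocyte markers summed to 10.8 and 29.7 CPM, neutrophil and lymphocyte markers to 0.0152 and 0.0691 CPM, and erythroid markers to 0 and 0.178 CPM. Smooth muscle and pericyte markers had a median of -0.76 (percentile 3.41; median length 3134 bases; length-adjusted -0.49), with 3 of 6 lower, 1 higher and Mcam at -2.57. Epicardial and mesothelial markers summed to 201 and 213 CPM and went both ways, with Lrrn4 at -3.33 and Upk3b at -2.14 against Aldh1a2 at 0.65; Tbx18 had -0.17. Their median was -1.16 over these 4 genes and 0.24 over the 2 genes left at a minimum of 20 CPM, and the list was called lower with library totals (-1.66 over 5 genes, percentile 0.2) and with no minimum (-1.40 over 11 genes, percentile 0.01). Chondrogenic and osteogenic markers had a median of 0.14 (percentile 77.9; median length 3524 bases; length-adjusted 0.51, percentile 98.4), with Alpl at 1.10 and Fmod at -1.28. Their median turned with the filter and the scaling, with -0.25 at a minimum of 1 CPM, -0.65 at 20 CPM and -0.74 with TPM.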

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

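The length corrections were chosen after the trend had been seen; the others were not. Among those others, list values kept a call 145 times, gained one 22 times and lost one 11 times (4 with a change of sign). Part of the 145 could hardly change, because a scaling factor shifts a list and its random lists alike. Another 45 list values without a call in either setting changed sign. Of named gene values, 989 stayed within their counting interval and 603 moved, with no change of sign among those past 2-fold in any scaling tried. Part of the 989 could hardly move, because the minimum CPM settings and leaving out predicted models keep the main scaling. Col1a1 had -1.348 in the main setting, at a minimum of 1 or 20 CPM, with no minimum and without predicted models. DESeq2 size factors shifted the median of all genes by only 0.0037. The 989 therefore does not measure how stable the folds are to scaling. With TPM and a pseudocount of 1, 112 genes were at least 2-fold higher and 1971 lower, Bcat1 had -4.00, and the medians were -0.31 for proline synthesis, -0.016 for antigen presentation and -0.077 for cholesterol synthesis; with a pseudocount of 0.1 these were 120, 2211, -6.00, -0.31, -0.016 and -0.077. The lower TPM medians go with a shift of genes in general. The shift of -0.41 in the overall median compares 8811 genes with TPM to 9935 in the main setting. With a pseudocount of 1, Col1a1 went from -1.348 to -1.852 and Acta2 from -0.107 to -0.612. The proline synthesis median moved much alike, from 0.19 to -0.31. Why TPM shifts the folds was not tested. With a minimum of 20 CPM, 352 genes were higher and 752 lower, since fewer genes enter; with no minimum, 2084 and 3086, and the cardiomyocyte markers had a median of 1.04 over mostly low counts. At 1.5-fold the counts were 1750 and 2544, and at 3-fold 94 and 452. The mean of the proline synthesis list was -0.13. With the length trend removed, 530 genes were lower, Bcat1 had -5.53, Fasn 0.087 and oxidative phosphorylation -0.030; with the implied length, 532, -5.16, 0.075 and -0.061, and TGF-beta 0.071; with length and GC content, 360 higher and 490 lower, Bcat1 -5.52, Fasn 0.30, oxidative phosphorylation -0.033, TGF-beta 0.10 and fatty acid genes 0.083. Keeping the row with the most counts could not apply, since each symbol has 1 row. No paired analysis was possible because each group has 1 library. A gene with 0 counts is not detectable below 0.0228 CPM in siControl and 0.0296 CPM in siBcat1.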

Other observations

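The tests of the length trend, of the interferon-stimulated genes and of the motif were chosen only after the result was seen, except those by expression level, with the 8-base site and of collagens without the motif. Intervals in the weighing of these patterns are bootstrap intervals over genes. Several groups not described so far did not stand apart from random lists. Cell cycle genes had a median of -0.27 (percentile 4.37; median length 3243 bases; length-adjusted -0.03), with 9 of 39 at least 1.5-fold lower and 3 higher, and Mki67 at -1.52 (length-adjusted -0.35), Foxm1 at -1.33 and Birc5 at 1.13; the list was called lower with TPM. Targets of p53 had 0.08 (percentile 69.9; median length 2771 bases; length-adjusted 0.22), with 5 of 20 higher and 4 lower, among them Bax at 1.13 (length-adjusted 0.40) and Sesn2 at -1.27. Glycolysis genes had 0.24 (percentile 79.6; median length 2848 bases; length-adjusted 0.20), with Ldhb at 1.00 and Hk1 at -1.04. Hypoxia targets had 0.18 (percentile 81.5; median length 2889 bases; length-adjusted 0.31), with Selenbp1 at 1.07. Genes of the citric acid cycle and glutamine had -0.04 (percentile 31.4; median length 2764 bases; length-adjusted -0.09), with Idh1 at 1.01 and Slc38a1 at -1.15.

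Growth factor genes and their receptors had a median of -0.02 (percentile 54.6; median length 2672 bases; length-adjusted -0.02) over members far apart, with Igfbp5 at -3.35 (length-adjusted -2.62) and Igfbp6 at 1.93 (length-adjusted 1.32). BMP and Wnt genes had -0.01 (percentile 44.2; median length 2576 bases; length-adjusted -0.27), with the secreted Wnt inhibitor gene Sfrp1 at -2.06, from 1541 to 368 CPM, and Id2 at 1.36. Immediate early genes had 0.14 (percentile 88.2; median length 2601 bases; length-adjusted 0.13), with Egr3 at -1.88 and Nr4a1 at -1.77. Metallothionein and heat shock genes had 0.17 (percentile 71.0; median length 2423 bases; length-adjusted 0.07), with Mt1 at 1.36 (length-adjusted 0.43). Lysosome and autophagy genes had 0.27 (percentile 88.6; median length 2353 bases; length-adjusted 0.12), with the cholesterol transfer genes Npc2 at 1.27 and Npc1 at -1.04. The medians of these groups and of the p53, glycolysis, hypoxia and citric acid cycle groups change sign with the scaling.

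Longer transcripts were lower with siBcat1. GC content and genomic span do not account for the trend, because the Spearman rho with length was -0.685 at fixed GC content and -0.541 at fixed genomic span. The trend ran through low, middle and high expression (weakest rho -0.620), which a difference in RNA integrity, RNA size or library preparation would give, as would an effect on long transcripts in the cells; with 1 library per group these cannot be told apart. The curve fitted over all genes does not account for the whole of the lower collagen values, whose median after its removal was -0.653 [-0.790 to -0.358]. With the GC trend removed as well, the median was -0.48. The random lists were matched on expression and not on length, and the interval is over genes of the same 2 libraries. A difference between the libraries that the curve misses therefore cannot be excluded.

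Interferon-stimulated genes were higher with siBcat1. The length trend does not account for it, since the median after its removal was 1.66 [1.09 to 2.13], nor do leukocytes in the culture, since 9 leukocyte genes together had 0.217 CPM in siBcat1 and 0.289 CPM in siControl, with Ptprc, Adgre1, C1qa and Tyrobp at 0 counts in both. The wider macrophage and monocyte list went the other way, with 10.8 and 29.7 CPM in siControl and siBcat1, mostly from Lyz2, and a median of 0.94 over 10 genes (percentile 98.5) with no expression minimum. A response to the siRNA itself may be the cause as well as loss of Bcat1, and with 1 siRNA against Bcat1 these cannot be told apart. The 15 type I interferon genes together had 0 counts in siControl and 0 in siBcat1, which does not bear on either.

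The 7-base word ATTCTGT in the 3' UTR went with lower values more than any other of 15724 words scored, on folds adjusted for transcript length and for 3' UTR length and GC content. Because the word was chosen on these folds, it was chosen again on a random part of the genes and tested on the remaining genes in 20 equal splits, which chose ATTCTGT 16 times and the overlapping TTCTGTA 4 times; the median of the remaining genes with the word was -0.066 or lower, with 0 of 1000 sets matched on 3' UTR length and GC content as low in any split, and the word ranked 2 or better among 210 orders of its bases, so neither property accounts for it. Unintended silencing through the siRNA seed, which would be ACAGAAT for this word, is a candidate explanation. Genes with the 8-base site ATTCTGTA differed in median by -0.147 [-0.239 to -0.078] from genes with the word alone. The Bcat1 transcript holds that site once, at base 1271 of 7833, before the 3' UTR that starts at base 1403. A transcript of that length can hold an 8-base site by chance, and 6.59% of the genes scored held this site in the 3' UTR. The siRNA sequence is not given in the sources used here. Genes with the word only outside the 3' UTR differed from those with it inside by 0.05 [-0.001 to 0.128]. For the 8-base site, 63 genes with it only outside the 3' UTR had a median of -0.171 [-0.243 to -0.071]. The 629 genes with it inside had -0.223 [-0.301 to -0.169]. Seed silencing and another property of these genes therefore cannot be told apart. Of the 100 lowest genes, 39 held the word and 17 the 8-base site, where 36.4 and 12.5 would at matched 3' UTRs. Sites of the word in the collagens' own 3' UTRs are not the whole cause of their lower values. The 15 collagens without the word there had a length-adjusted median of -0.653 [-0.790 to -0.290]. These 15 can hold shorter matches, as Col12a1 does with the last 6 bases of the word, while Col1a1, Col1a2 and Col3a1 held none in the 3' UTR. The 4 collagens with the word had a length-adjusted median of -0.586. Col14a1, the lowest collagen, held the 8-base site in its 3' UTR. Among other genes named above, so did Celf2, Tgfb2, Deptor, Sfrp1, Txnrd1, Dhcr7 and Tbx18, which were lower, and Hnrnpa1, which was higher. Whether the site moved these genes was not tested. Silencing of another gene that acts on the collagens was not tested.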
